A study of Homo sapiens with 9 samples.

How the data were processed

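RNA sequencing libraries were examined from 9 samples of cells that the labels give as a carboplatin-resistant form of the human retinoblastoma line Weri-RB1. The labels put 3 libraries in each of 3 groups. The control group carried a non-targeting short hairpin RNA (shNC), and the other groups carried shSNHG1#1 or shSNHG1#2, hairpins designed against the long noncoding RNA gene SNHG1. Cells were grown in RPMI medium with fetal bovine serum, RNA was extracted with Trizol and libraries were made with a BGI protocol, per the labels' protocols. The labels give no cell density, medium age, time after delivery of the hairpins or library batch.

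The deposited table holds, per the file headers, an estimated read count and an FPKM value for each of 27407 features in each library. Estimated counts need not be whole numbers, because the authors' counting shared reads among transcripts. FPKM values, deposited by the authors, are fragments per kilobase of transcript, scaled to the mapped fragments of the library. HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 are named in the submitters' processing notes, with no role given for each. The genome build, the annotation and the use of strand in counting are not given in the sources used here, so no coordinates are printed, and values of overlapping genes or near-identical copies are uncertain. Of 23603 Entrez gene identifiers in the table, 22938 matched the RefSeq annotation of assembly GRCh38.p14, which was used only for gene names and the order of neighbouring genes. The other 3804 features have no gene symbol. SNHG1 was not analysed here.

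Total estimated counts lay between 21502093 and 21606498 per library, so depth differed little between libraries. Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Scaling used TMM factors, and filterByExpr on the 3 groups kept 18767 features, 17573 of them with a gene symbol. A quasi-likelihood F test was fitted to all 9 libraries with group as the only term, and each contrast was adjusted by the Benjamini-Hochberg method. An adjusted p below 0.05 was the threshold. Standard errors of log2 fold changes were derived from the F statistic. The median biological coefficient of variation was 9.65%. FPKM levels are given as mean ± SD with n = 3. Intervals for ratios of low counts are exact at 95% and cover counting error only. A fold against libraries that all had 0 counts was computed against a floor of 3 counts over the group.

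Before the data were examined, 34 lists of genes were fixed for the processes and cell types that the cells and the target could involve, and 33 had at least 5 tested members. Lists were tested with camera of limma 3.58.1 on log2 CPM (scaled counts) with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists. Camera with a correlation estimated from the data and the self-contained test fry were run beside it. The genes named were fixed by rule, with SNHG1 to come first. The rule took genes past the threshold with both hairpins in the same direction and a mean log2 CPM of at least 2, the 8 with the highest and the 8 with the lowest mean log2 fold change. To these it added, for each contrast, the 5 highest and 5 lowest log2 fold changes among genes past the threshold with the same minimum level whose libraries of 1 group all lay above those of the other, and up to 4 members of each list with the smallest p in each contrast against shNC. The text gives only part of the genes that the rule named, picked after their values were seen, and the rest are not reported here. Genes outside the rule whose values are given are marked as chosen after their values were seen.

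The contrasts against shNC share their control libraries. To show what this alone gives, 20 pairs of unchanged groups were simulated against simulated controls. The tests were also checked on simulated counts for 18767 features with 200 genes changed, as many higher as lower. The changed genes were drawn only from those with a mean log2 CPM of at least 2. The check thus does not cover genes below that level, or scaling when as many genes change as in these data. For shSNHG1#1 against shNC, 86.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. For shSNHG1#2 against shNC the shares were 79.1%, 95.5% and 100%, and for shSNHG1#2 against shSNHG1#1 they were 85.1%, 92.5% and 100%. Among the calls, 5.56%, 4.69% and 6.09% were unchanged genes. Of the simulated lists, 5 of 5 changed and 0 of 20 unchanged were called in each comparison. Genes were simulated as independent of each other, so this check does not cover false calls from correlation between the genes of a list. In the data the estimated correlation was 0.449 for ribosomal protein genes and 0.543 for immediate early genes.

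Replicates of a group were compared by a chi-square test over features with at least 50 counts. The statistic per degree of freedom was 3.06 to 6.50 for the 9 pairs. No library was thus a copy of another of its group, but technical repeats are not excluded. Alternatives were DESeq2 size factors, library totals alone, the DESeq2 1.42.0 Wald test, other count filters, a minimum fold change, the replicate number as a term, fits to the 2 groups compared, and leaving out each library in turn. Alternatives for files of normalized values did not apply, since the table holds counts. Alternatives on the SNHG1 level were not run.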

Results

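Transcript levels were measured by RNA sequencing in cells labelled as Weri-RB1/CRP, a carboplatin-resistant form of a retinoblastoma line. Retinoblastoma is a childhood tumour of the retina, and carboplatin is a platinum drug that crosslinks DNA. SNHG1 is a long noncoding RNA gene that also hosts small nucleolar RNAs, and the series title places it in resistance to carboplatin. Short hairpin RNAs are processed into small RNAs that lower transcripts of matching sequence. The control shNC and the hairpins shSNHG1#1 and shSNHG1#2 had 3 libraries each, and total estimated counts ran from 21502093 to 21606498 per library. No library is labelled as exposed to carboplatin or as the parental line. SNHG1 was not analysed here, so its knockdown is not checked by these values and groups follow the labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

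Transcripts of photoreceptors were near 0 in all 3 groups. Of 30 genes of the cone photoreceptor list in the table, 25 had a mean below 1 FPKM in every group, and so had 17 of 21 rod photoreceptor genes. CRX, a transcription factor of photoreceptors, did not exceed 0.03 FPKM in any library, and RCVRN, which encodes recoverin, did not exceed 0.09 FPKM. MYCN reached at most 0.08 FPKM. The cone genes at 1 FPKM or more in some group were GNAT2, GRK7, ISL2, SLC24A2 and THRB, and the rod genes were GNB1, NR2E3, REEP6 and SLC24A1. GNAT2, a cone transducin subunit, stood at 18.6 ± 0.874 FPKM (SD, n = 3) in shNC. In contrast, the epithelial keratin gene KRT8 stood at 783 ± 2.49 FPKM and KRT18 at 762 ± 3.91 FPKM in shNC. RB1, the tumour suppressor gene lost in most retinoblastomas, lay between 12.9 and 14.7 FPKM over the 9 libraries. CRX, RCVRN, MYCN, ISL2, SLC24A2, NR2E3, KRT8, KRT18 and RB1 were chosen after their values were seen. These levels hold for every comparison that follows.

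**Figure D1:**
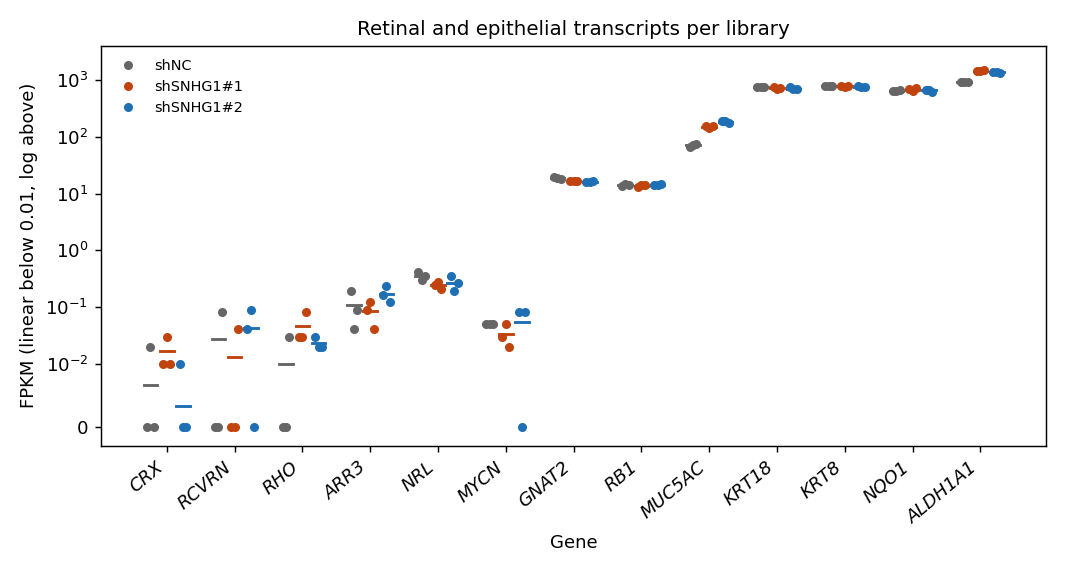
FPKM of retinal genes (CRX to GNAT2), RB1 and epithelial or detoxification genes (MUC5AC to ALDH1A1), chosen after their values were seen, on an axis that is linear below 0.01 and logarithmic above. Points are libraries and short lines are means of 3 libraries per group; CRX stays at or below 0.03 FPKM and KRT8 at or above 745 FPKM.

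With shSNHG1#1, genes of hypoxia and glycolysis fell against shNC and genes of cell division rose. Of 35 tested hypoxia and glycolysis genes, 33 fell and 2 rose, with a median log2 fold change of -1.56. ADM, which encodes the vasodilator peptide adrenomedullin, fell 7.62-fold from 284 ± 3.13 to 38.0 ± 1.92 FPKM (SD, n = 3; log2 fold change -2.93, SE 0.03, adjusted p = 8.6e-13). The glycolytic enzyme genes ALDOC, HK2 and PGK1 were lower 8.60-fold, 6.12-fold and 3.57-fold, and PDK1, whose kinase holds pyruvate out of the citric acid cycle, was lower 6.56-fold. The members that rose were HK1 (log2 fold change 0.18) and PFKM (0.38), chosen after their values were seen. All 35 members also passed when adjusted over the list alone, and the list stood apart from other genes by camera (adjusted p = 3.3e-27).

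Of 41 genes of DNA replication and the G1/S transition, 40 rose with shSNHG1#1 and 0 fell (camera, adjusted p = 4.0e-18; 40 adjusted over the list alone). CCNE1, which encodes cyclin E1, rose 3.37-fold from 5.26 ± 0.355 to 18.3 ± 1.56 FPKM. The helicase subunit gene MCM4 rose 2.21-fold and RRM2, a subunit of ribonucleotide reductase, 2.08-fold. Among 42 genes of mitosis and G2/M, 40 rose and 1, ANLN, fell by 0.15 on the log2 scale (camera, adjusted p = 8.3e-16; 42 adjusted over the list alone). CDK1 rose 1.66-fold and AURKA 1.64-fold. ANLN was chosen after its values were seen. Of 32 genes of Fanconi and homologous recombination repair, which act on DNA crosslinks, 24 rose, among them UBE2T (2.204-fold) and FANCI (1.56-fold). FANCF, FANCL and RAD54B fell, and were chosen after their values were seen. FANCL lost its call without shNC replicate 1, shSNHG1#1 replicate 1 or shSNHG1#1 replicate 3, with adjusted p up to 0.0773. This list passed camera with the preset correlation (adjusted p = 5.2e-05; 28 adjusted over the list alone) but not with an estimated correlation (adjusted p = 0.317).

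Signalling and defence genes were lower with shSNHG1#1. Of 46 interferon-stimulated genes, 37 fell and 3 rose (camera, adjusted p = 4.9e-16; 41 adjusted over the list alone). IRF9, part of the complex that carries interferon signals to the nucleus, fell 2.57-fold, and the antiviral GTPase gene MX1 fell 1.90-fold from 188 ± 4.07 to 102 ± 0.303 FPKM. DDX60, IFI44 and OASL rose, and were chosen after their values were seen. Of 25 NF-kB and inflammatory genes, 16 fell and 3 rose (adjusted p = 5.6e-05; 19 adjusted over the list alone), with the chemokine gene CXCL8 down 2.17-fold and TNFAIP3, an inhibitor of NF-kB signalling, down 1.90-fold. SOD2, TNFAIP2 and VCAM1 rose and were chosen after their values were seen. Of 26 immediate early genes, 16 fell and 3 rose (adjusted p = 1.0e-04; 19 adjusted over the list alone; adjusted p = 0.598 with an estimated correlation). EGR1 fell 6.48-fold to 12.35 ± 6.62 FPKM, a wide spread between the shSNHG1#1 libraries, and DUSP1 fell 4.42-fold. DUSP6, KLF4 and SPRY4, chosen after their values were seen, rose. FOS was 3.92-fold lower, and 8.36-fold lower without shSNHG1#1 replicate 1, whose level of 23.7 FPKM stood above 5.77 and 5.27 FPKM in the other shSNHG1#1 libraries. Of 75 cytosolic ribosomal protein genes, 31 fell and 1, RPLP0, rose (adjusted p = 5.3e-04; 32 adjusted over the list alone; adjusted p = 0.630 with an estimated correlation). The median log2 fold change of this list was only -0.107, and -0.061 when scaled by library totals alone. RPLP0 was chosen after its values were seen, and lost its call without shSNHG1#1 replicate 3 (adjusted p = 0.0558).

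In all, 9023 of 18767 genes passed the threshold in edgeR's quasi-likelihood test of shSNHG1#1 against shNC, 4606 higher and 4417 lower. Scaled by library totals alone, without TMM factors, 5264 were higher and 3819 lower, which is 58.0% higher against 51.0%. A change of at least 2-fold was seen for 1159 of them, 658 higher and 501 lower. The 3 libraries of 1 group all lay above those of the other for 56.3% of genes, where chance gives 10%. Of 33 lists, 8 passed with the preset correlation and 5 of these with an estimated one. Camera with an estimated correlation gave far larger adjusted p: 0.0025 for hypoxia and glycolysis, 0.0013 for DNA replication and 0.0298 for mitosis. It gave 0.0044 for interferon-stimulated and 0.0224 for NF-kB genes.

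**Figure D2:**
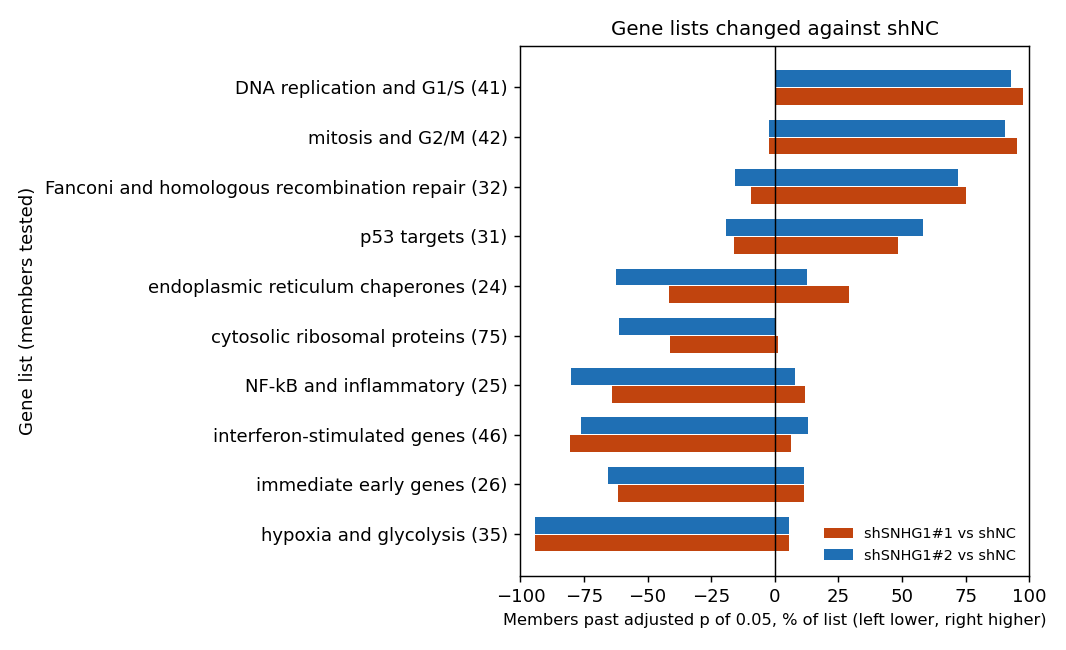
Share of the tested members of each list that passed an adjusted p of 0.05 against shNC, lower to the left and higher to the right, for the 10 lists called with either hairpin. With both hairpins, 33 of 35 hypoxia and glycolysis genes were lower, and 40 (shSNHG1#1) or 38 (shSNHG1#2) of 41 replication genes were higher.

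With shSNHG1#2, hypoxia and glycolysis genes were also lower and cell division genes higher than in shNC. Of the 35 hypoxia and glycolysis genes, 33 fell and HK1 and PFKM rose, with a median log2 fold change of -1.47 (camera, adjusted p = 2.4e-28; 35 adjusted over the list alone). ADM fell 5.64-fold to 52.4 ± 0.391 FPKM (SD, n = 3; log2 fold change -2.50, SE 0.03, adjusted p = 6.5e-12), ALDOC 9.45-fold and HK2 4.75-fold. NDRG1, a stress-response gene induced by hypoxia, fell 3.23-fold from 964 ± 17.9 to 322 ± 3.86 FPKM. DNA replication and G1/S genes rose in 38 of 41 cases with 0 lower (adjusted p = 1.8e-18; 40 adjusted over the list alone), CCNE1 by 3.15-fold and MCM4 by 2.08-fold. Mitosis and G2/M genes rose in 38 of 42 cases, while ANLN fell (adjusted p = 2.9e-13; 39 adjusted over the list alone). Fanconi and homologous recombination genes rose in 23 of 32 cases, UBE2T by 2.12-fold, and fell in 5, FANCF, FANCL, RAD50, RAD51B and RAD54B (adjusted p = 1.1e-05; 31 adjusted over the list alone; adjusted p = 0.189 with an estimated correlation). RAD50 and RAD51B were chosen after their values were seen. Leaving out 1 library ended the calls of FANCL, RAD50, RAD51B and RAD54B, with the highest adjusted p at 0.0609 without shSNHG1#2 replicate 1, 0.168 without shSNHG1#2 replicate 1, 0.0848 without shNC replicate 1 and 0.106 without shSNHG1#2 replicate 2.

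Interferon-stimulated genes fell in 35 of 46 cases with shSNHG1#2 and rose in 6 (adjusted p = 2.2e-09; 43 adjusted over the list alone), with IRF9 down 1.92-fold and MX1 down 1.396-fold. NF-kB and inflammatory genes fell in 20 of 25 cases and rose in 2, TNFAIP2 and VCAM1 (adjusted p = 2.0e-08; 22 adjusted over the list alone), and LIF, a cytokine gene, fell 2.04-fold. Immediate early genes fell in 17 of 26 cases, EGR1 by 7.29-fold and FOS by 7.22-fold, while DUSP6, KLF4 and SPRY4 rose (adjusted p = 7.05e-06; 20 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation). Ribosomal protein genes fell in 46 of 75 cases with 0 higher (adjusted p = 9.6e-09; 48 adjusted over the list alone; adjusted p = 0.486 with an estimated correlation). Their median log2 fold change was only -0.169, and -0.103 when scaled by library totals alone. Endoplasmic reticulum chaperone genes fell in 15 of 24 cases and rose in 3, CRELD2, HYOU1 and SYVN1, chosen after their values were seen (adjusted p = 0.00173; 18 adjusted over the list alone; adjusted p = 0.0571 with an estimated correlation). The median of the chaperone list was a log2 fold change of -0.137, and -0.072 when scaled by library totals alone. Leaving out 1 library ended the calls of TNFAIP2, with the highest adjusted p at 0.173 without shNC replicate 2, and of HYOU1, at 0.0511 without shNC replicate 3. HERPUD1, which serves the degradation of misfolded proteins of the endoplasmic reticulum, fell 3.20-fold. Of 31 p53 targets, 18 rose and 6 fell (adjusted p = 0.0052; 24 adjusted over the list alone; adjusted p = 0.0721 with an estimated correlation). The metabolic regulator gene TIGAR rose 1.89-fold and PMAIP1, which promotes apoptosis, 1.74-fold, while PLK2 fell 1.45-fold. With shSNHG1#1, 15 p53 targets rose and 5 fell, and the list did not pass (adjusted p = 0.0506; 20 adjusted over the list alone).

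Against shNC, 8669 genes passed with shSNHG1#2, 4382 higher and 4287 lower, and 992 of them changed at least 2-fold, 562 higher and 430 lower. By library totals alone, 5344 were higher and 3426 lower, which is 60.9% higher against 50.5%. The 3 libraries of 1 group all lay above those of the other for 55.8% of genes, where chance gives 10%. Of 33 lists, 10 passed and 5 of these also with an estimated correlation. Camera then gave adjusted p of 0.0022 for hypoxia and glycolysis, 0.0013 for DNA replication and 0.0446 for mitosis. It gave 0.0148 for interferon-stimulated and 0.0066 for NF-kB genes.

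**Figure D3:**
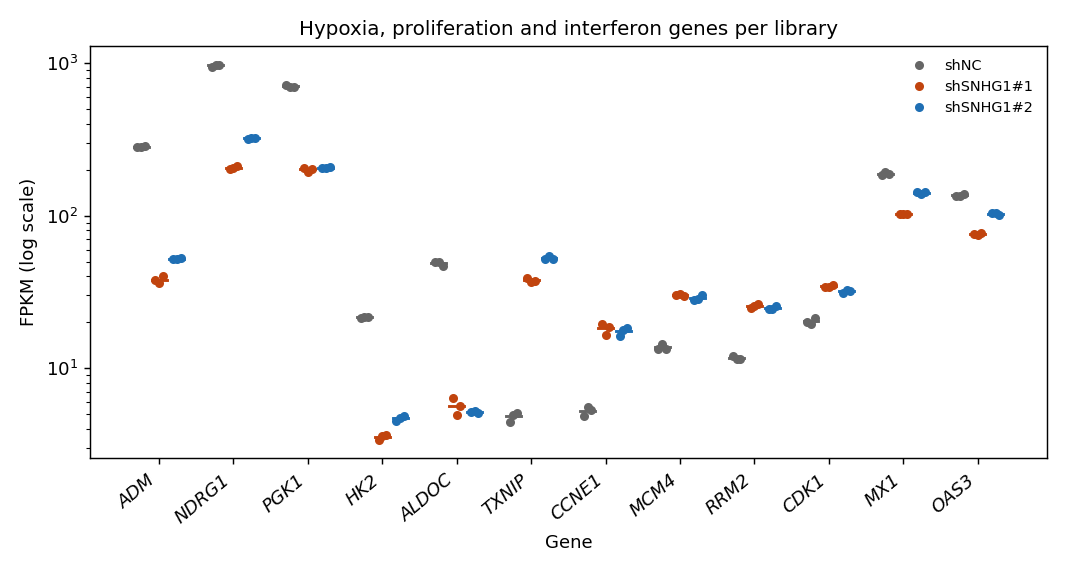
FPKM on a logarithmic axis for genes of hypoxia and glycolysis (ADM, NDRG1, PGK1, HK2, ALDOC), TXNIP, cell division (CCNE1, MCM4, RRM2, CDK1) and interferon response (MX1, OAS3). Points are libraries and short lines are means of 3 libraries per group; MX1 stands at 188 FPKM in shNC, 102 FPKM with shSNHG1#1 and 141 FPKM with shSNHG1#2.

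Many of the same genes differed from shNC with both hairpins. Among genes that rose with both, TXNIP, which encodes an inhibitor of thioredoxin that responds to glucose, went from 4.86 ± 0.339 FPKM in shNC to 37.6 ± 1.11 with shSNHG1#1 and 53.1 ± 1.36 with shSNHG1#2 (SD, n = 3), and its relative ARRDC4 rose 5.35-fold and 7.45-fold. The intestinal mucin gene MUC2 rose 8.62-fold and 8.90-fold, and DHRS2, a dehydrogenase gene, 5.16-fold and 7.44-fold. Among genes that fell with both, STC2, a stress-induced glycoprotein gene, went from 91.1 ± 0.341 FPKM to 15.96 ± 0.113 and 17.5 ± 1.16. The stress genes DDIT3 (3.06-fold and 2.91-fold), DDIT4 (2.83-fold and 3.02-fold) and PPP1R15A (3.03-fold and 2.93-fold) were lower, although the list of the integrated stress response did not pass, with 17 of 37 members higher and 12 lower with shSNHG1#1 (29 adjusted over the list alone) and 16 higher and 16 lower with shSNHG1#2 (33 adjusted over the list alone). The oncogene MYC fell from 58.0 ± 0.929 FPKM to 20.9 ± 0.840 and 23.7 ± 0.582. Heat shock genes went both ways: HSPA6 fell from 14.6 ± 0.478 FPKM to 0.223 ± 0.159 and 0.193 ± 0.131 and DNAJB1 fell 2.78-fold and 2.82-fold, whereas STIP1 rose 1.57-fold and 1.47-fold. The fold of HSPA6 rests on few counts, and it was 67.0 with shSNHG1#1 but 108 without replicate 1 of that group, and 76.7 with shSNHG1#2 but 117 without its replicate 2. HSPA1A fell 2.75-fold and 2.78-fold, with reads it may share with HSPA1B. The histone gene HIST1H2BC had 314 counts over the 3 shNC libraries and 0 over the 6 others, so it was at least 104-fold lower with each hairpin, against a floor of 3 counts over a group, and reads shared among histone copies make it uncertain.

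In total, 7500 genes passed with both hairpins in the same direction, 3811 higher and 3689 lower, and 10 passed in opposite directions. By library totals alone, 4533 were higher and 3031 lower. For 110 genes followed singly, most of them picked because they had passed, all 3 libraries of each hairpin lay on 1 side of the shNC libraries, which for SOD2 was the upper side with shSNHG1#1 and the lower side with shSNHG1#2. Independent lists of the same sizes would share 1075 higher and 1009 lower genes, and in 20 simulations of unchanged groups against shared controls at most 1 gene was called with both in the same direction. Each unchanged group had at most 2 genes called in any simulation. That overlap was thus small by construction, and it does not show how much of the 7500 comes from sharing controls. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.760 against a mean of 0.505 in the simulations and a covariance of 0.330 against 0.0583, a difference of 0.272. The sign was shared by 86.8% of genes, against 66.9% in the simulations. The 3 control libraries are too few to divide, and part of the excess may come from the shared controls. The simulations hold only spread between libraries. A shift common to the shNC libraries would also appear in both contrasts and is not covered by them.

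**Figure D4:**
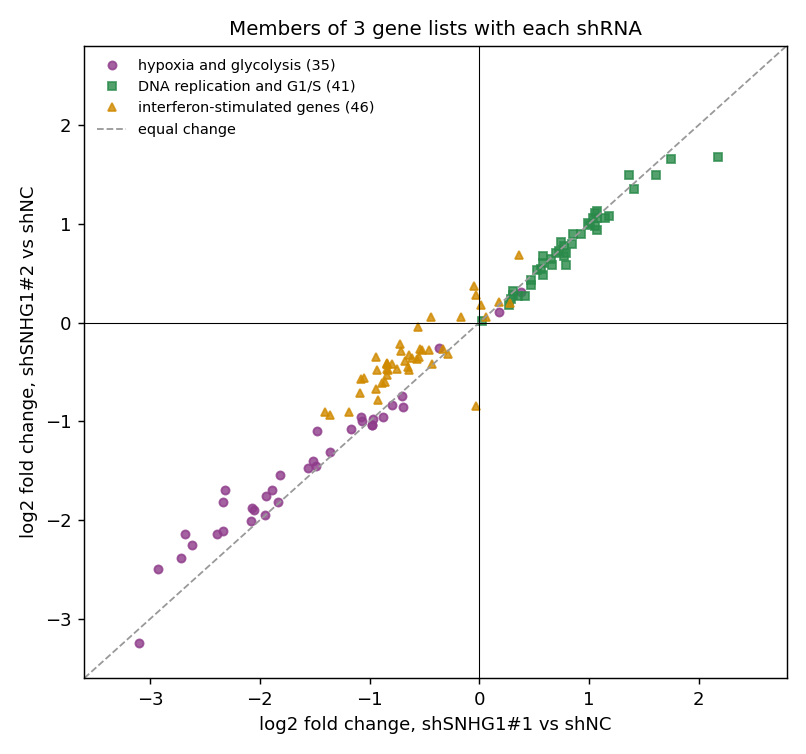
The log2 fold change with shSNHG1#2 plotted against that with shSNHG1#1, both against the same shNC libraries, for the tested members of 3 lists, with a dashed line where both are equal. Median changes of hypoxia and glycolysis genes were -1.56 and -1.47, those of DNA replication genes 0.78 and 0.72, and those of interferon-stimulated genes -0.66 and -0.40.

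Around SNHG1, 3 of the protein-coding neighbours changed with both hairpins by several fold. In the RefSeq order TMEM223, TAF6L, TMEM179B, NXF1, STX5 and WDR74 precede SNHG1. NXF1, which exports messenger RNA from the nucleus, fell from 56.6 ± 1.28 FPKM to 15.8 ± 0.435 with shSNHG1#1 and 15.4 ± 0.484 with shSNHG1#2 (SD, n = 3; adjusted p = 4.3e-12 and 8.2e-12). By counts, on which the test rests, NXF1 fell 5.29-fold and 5.06-fold, more than by FPKM. WDR74, a ribosome assembly factor, fell from 50.7 ± 2.02 FPKM to 13.5 ± 1.35 and 14.2 ± 0.827. STX5, a syntaxin of the Golgi, had 1 count over the shNC libraries, 1366 over the shSNHG1#1 libraries and 1483 over the shSNHG1#2 libraries. That count lay in shNC replicate 2, and without this library the fitted log2 fold changes, which depend on the prior count and are no bounds, moved from 9.92 to 11.83 and from 10.02 to 11.93. The ratios were 1366 (95% exact interval 245 to 53990) and 1484 (266 to 58662). SLC3A2 fell 1.34-fold and 1.37-fold. The length of NXF1 implied by its counts and FPKM was 11862 to 11917 bases in shNC and 8006 to 9139 bases in the other libraries, so its value, and that of STX5, depends on how reads were shared between transcripts. Of 11 tested genes in the list of neighbours, 3 were higher and 3 lower with shSNHG1#1, 2 higher and 4 lower with shSNHG1#2, and the list did not pass with either (adjusted p = 0.645 and 0.589; 6 and 6 adjusted over the list alone). The snoRNA host genes SNHG7 and SNHG12 fell 1.90-fold and 1.52-fold with shSNHG1#1 and 1.69-fold and 1.31-fold with shSNHG1#2, and the list of 13 tested hosts did not pass (adjusted p = 0.342 and 0.360; 6 and 7 adjusted over the list alone).

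**Figure D5:**
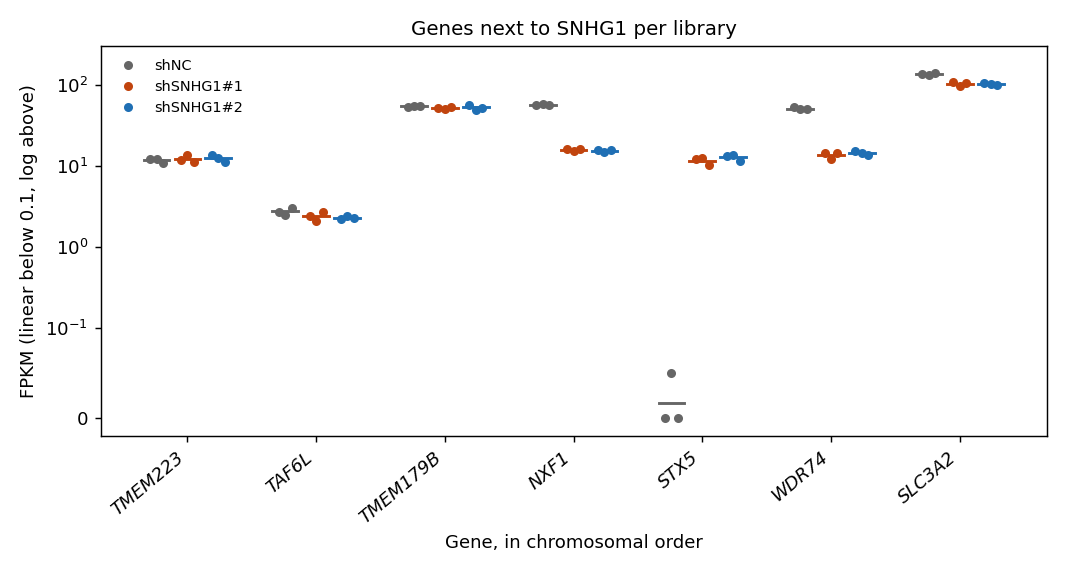
FPKM of tested neighbours of SNHG1 in chromosomal order, with 5 of the listed neighbours left out, on an axis that is linear below 0.1 and logarithmic above. Points are libraries and short lines are means of 3 libraries per group; NXF1 and WDR74 are lower and STX5 is higher in the 6 shSNHG1 libraries than in shNC.

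The lists of platinum and drug transport, glutathione and metallothionein, nucleotide excision repair and apoptosis genes did not pass against shNC with either hairpin. The copper transporter gene SLC31A1, whose product also takes up platinum drugs, rose 1.72-fold with shSNHG1#1 and 1.57-fold with shSNHG1#2, from 4.81 ± 0.160 FPKM in shNC to 8.61 ± 0.110 and 7.98 ± 0.232 (SD, n = 3). The copper exporter ATP7A fell 1.51-fold and 1.42-fold while ATP7B rose 1.71-fold and 1.75-fold. ABCC2, an export pump, fell 1.12-fold and 1.14-fold, and SLC47A1 rose 1.53-fold and 1.46-fold. With each hairpin 8 of 17 transport genes rose and 3 fell (adjusted p = 0.166 and 0.282; 11 and 11 adjusted over the list alone). GCLC, the catalytic subunit of the enzyme that limits glutathione synthesis, fell from 150 ± 1.43 to 55.8 ± 1.32 and 58.4 ± 0.384 FPKM, whereas GCLM, its other subunit, rose 1.34-fold and 1.27-fold. Glutathione and metallothionein genes rose in 12 of 25 cases and fell in 6 with shSNHG1#1, and rose in 7 and fell in 8 with shSNHG1#2 (adjusted p = 0.796 and 0.961; 18 and 16 adjusted over the list alone). Nucleotide excision repair genes rose in 10 of 23 cases and fell in 3 with shSNHG1#1, and rose in 8 and fell in 3 with shSNHG1#2 (adjusted p = 0.330 and 0.317; 14 and 11 adjusted over the list alone). LIG1, a DNA ligase gene, rose 1.38-fold and 1.44-fold, and GTF2H1 fell 1.54-fold and 1.53-fold. Apoptosis regulators rose in 11 of 35 cases and fell in 8 with shSNHG1#1, and rose in 10 and fell in 9 with shSNHG1#2 (adjusted p = 0.565 and 0.591; 19 and 19 adjusted over the list alone). BIRC5, which encodes survivin, rose 1.66-fold and 1.35-fold, BCL2L11 rose 1.47-fold and 1.36-fold, and BIRC2 fell 1.52-fold and 1.33-fold.

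No list of retinal, glial, mesenchymal, blood or neuronal cell types passed against shNC with either hairpin. The smallest adjusted p among these was 0.163 with shSNHG1#1, for retinal progenitor genes, of which 7 of 11 were higher and 1 lower, and 0.0683 with shSNHG1#2, for fibroblast and mesenchymal genes, of which 4 of 29 were higher and 10 lower. Many retinal genes were absent or too low to test. Only 8 of 33 cone, 13 of 21 rod and 6 of 14 retinal pigment epithelium genes were tested. For these lists a failure to pass therefore says little about an effect of the hairpins. SOX2 rose 1.47-fold and 1.99-fold, and PAX6 2.60-fold and 3.22-fold from 0.347 ± 0.181 FPKM in shNC. Among mesenchymal genes, FN1 fell from 716 ± 5.85 FPKM to 319 ± 7.45 and 407 ± 3.29. In all, 25 lists did not pass with shSNHG1#1 and 23 did not with shSNHG1#2. The median, the mean and the test did not share a sign for 8 and 7 lists, none of them called. In fry, which asks only whether the genes of a list move on balance in 1 direction, 28 and 32 of 33 lists passed.

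The hairpins differed from each other in the size of the interferon response. Of 46 interferon-stimulated genes, 29 were higher with shSNHG1#2 than with shSNHG1#1 and 0 lower (camera, adjusted p = 4.6e-42; 39 adjusted over the list alone). Camera with an estimated correlation gave this list an adjusted p of 7.8e-04. MX1 was 1.36-fold, OAS3 1.33-fold, IRF9 1.34-fold and PARP9 1.41-fold higher with shSNHG1#2, and all 4 were below shNC with both hairpins. Hypoxia and glycolysis genes were higher with shSNHG1#2 in 13 of 35 cases and lower in 1, ENO1 (adjusted p = 7.6e-09; 21 adjusted over the list alone), with NDRG1 1.54-fold higher. LOX, which crosslinks collagen, was at 4.26 ± 0.0862 FPKM with shSNHG1#2 and 2.18 ± 0.0681 with shSNHG1#1 (SD, n = 3; log2 fold change 0.94, SE 0.06, adjusted p = 2.4e-05). The calcium channel gene CACNA1B was 1.82-fold and the metallothionein gene MT1X 1.59-fold higher with shSNHG1#2. The lists of endoplasmic reticulum chaperones (adjusted p = 1.0e-08) and cholesterol synthesis (adjusted p = 2.6e-04) passed towards lower with shSNHG1#2. Few members passed singly, with 2 of 24 chaperone genes lower, DERL1 and PDIA4, and 0 higher (12 adjusted over the list alone), and 2 of 25 cholesterol synthesis genes lower, FDPS and INSIG1, and 0 higher (5 adjusted over the list alone). ENO1, DERL1, PDIA4, FDPS and INSIG1 were chosen after their values were seen, and leaving out 1 library ended each of these calls, with the highest adjusted p at 0.0738, 0.219 and 0.139 for ENO1, DERL1 and PDIA4 without shSNHG1#2 replicate 2, 0.0574 for FDPS without shSNHG1#1 replicate 3 and 0.0894 for INSIG1 without shSNHG1#2 replicate 3.

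Surfactant genes of the lung were highest in a single library and near 0 with shSNHG1#2 alone. SFTPC had 2855 counts in shSNHG1#1 replicate 1, and the sum of SFTPA1, SFTPA2, SFTPB and SFTPC was 10274 counts there, 387 and 367 in the other shSNHG1#1 libraries, 403 to 645 in shNC and 3 to 11 with shSNHG1#2. Between the hairpins, SFTPC, SFTPA1 and SFTPB passed narrowly (adjusted p = 0.042, 0.045 and 0.035) with log2 fold changes of -9.83, -9.49 and -7.44. Without shSNHG1#1 replicate 1 these changes were -6.39, -6.05 and -4.52. The calls were then stronger in edgeR's test, with adjusted p of 3.9e-04, 9.5e-04 and 9.7e-05. SFTPC and SFTPA1 each had 3 counts over the shSNHG1#2 libraries, so their fitted changes depend on the prior count, and without shSNHG1#2 replicate 1 they were -12.96 and -10.32. The ratios of shSNHG1#1 to shSNHG1#2 were 1013 (95% exact interval 346 to 4915) for SFTPC and 799 (273 to 3879) for SFTPA1. Leaving out an shNC or an shSNHG1#2 library ended each of these calls, with adjusted p up to 0.176 for SFTPA1 without shSNHG1#2 replicate 2. The changes in those fits were -9.28 to -12.96 for SFTPC, -8.94 to -10.32 for SFTPA1 and -7.17 to -7.58 for SFTPB. Reads that SFTPA1 and SFTPA2, the latter chosen after its values were seen, may share make both uncertain. Of the 37 genes that differed at least 2-fold between the hairpins, 27 had their highest value of all 9 libraries in shSNHG1#1 replicate 1. The mediator subunit gene MED4 was 2.15-fold higher with shSNHG1#2 (adjusted p = 0.045), a call that 8 of the 9 fits without 1 library lost, with adjusted p up to 0.146 without shSNHG1#2 replicate 2.

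Between the hairpins 586 genes passed, 375 higher with shSNHG1#2 and 211 lower, and 37 of them changed at least 2-fold, 6 higher and 31 lower. Without shSNHG1#1 replicate 3, shSNHG1#2 replicate 2 or shSNHG1#2 replicate 3 the count was 351, 297 or 349, and DESeq2 gave 970. Scaled by library totals alone, 431 were higher and 145 lower, which is 74.8% higher against 64.0%. Of 33 lists, 11 passed. The lists of interferon-stimulated, hypoxia and glycolysis, endoplasmic reticulum chaperone and cholesterol synthesis genes also passed with an estimated correlation. For these lists camera then gave adjusted p of 7.8e-04, 0.0340, 0.0118 and 0.0340, in that order. The other 7 were lower with shSNHG1#2 and did not, with adjusted p = 0.0563 for mitosis and G2/M, 0.0621 for NF-kB and inflammatory, 0.0846 for cytosolic heat shock, 0.117 for the integrated stress response, 0.389 for glutathione and metallothionein, 0.461 for ribosomal proteins and 0.608 for blood and immune genes with an estimated correlation. Of these 7, leaving out 1 library also ended the call of the glutathione and metallothionein list (adjusted p up to 0.329, without shSNHG1#2 replicate 3), of the integrated stress response (up to 0.0986, without shSNHG1#2 replicate 2) and of blood and immune genes (0.126, without shSNHG1#1 replicate 1). The mean of the glutathione and metallothionein list was above 0, at 0.016, while its median and test were below 0.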

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

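The test of the difference between the hairpins was planned, and the tests of explanations for photoreceptor transcripts, for the neighbours of SNHG1 and for lung transcripts, like the limits set for other splits of the libraries, were chosen only after the results were seen.

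Photoreceptor transcripts were near 0 in libraries labelled as a retinoblastoma line, with 25 of 30 cone genes under 1 FPKM in every group. Too little depth is argued against: 3 counts stood for at most 0.424 FPKM in any cone gene, so a level of 1 FPKM would have been seen. A loss of retinal transcripts in Weri-RB1 cells, the biological explanation, is argued against by RB1, which had 12.9 FPKM or more in every library. Weri-RB1 is known to lack this gene through a deletion, which rests on knowledge outside these data. Cells of another origin than the retina may account for the pattern but cannot be told apart from other retinal tumour cells that lost these transcripts, and a library set under a wrong name stays open. The count of 25 is the pattern itself, and of the lists of other cell types fixed beforehand, the fibroblast and mesenchymal list had 8 of 32 genes and the blood and immune list 1 of 16 at 10 FPKM or more in every library. Apart from retinal pigment epithelium, no list fixed beforehand covered epithelial cells, so these counts do not bear on an epithelial origin. The epithelial keratin genes KRT8 and KRT18, chosen after their values were seen, were at 745 and 684 FPKM or more in every library. No parental line was among the groups.

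NXF1 and WDR74 were lower with both hairpins, while STX5 was near 0 in shNC alone. If reads had only moved between NXF1, STX5 and WDR74, their summed scaled counts would have kept their level, but they fell to at most 0.235 of shNC. A lower output of the whole neighbourhood is also argued against, since the lower of the medians over the 8 other tested neighbours was a log2 fold change of -0.016. For STX5, reads counted under a long NXF1 transcript in shNC may be the cause, since the NXF1 length implied in shNC was at least 1.30 times that in any shSNHG1 library. A change of NXF1 and WDR74 by the hairpins themselves or by lower SNHG1 stays open. The sum covers only NXF1, STX5 and WDR74, so it cannot tell whether reads of other transcripts were counted under them.

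Lung surfactant transcripts were high in shSNHG1#1 replicate 1. In the blood and immune list, fixed beforehand, 13 of 16 genes had their highest scaled count in that library, where 1 library of 9 would hold 1.78 by chance. CD68, at 3579 counts there, was higher in every shNC library. Of the 16, 5 were at 1 FPKM or more with shSNHG1#2 and 5 are also in the lung tissue list below. In the fibroblast and mesenchymal list, 16 of 32 genes were highest there, and 21 of the 32 were at 1 FPKM or more with shSNHG1#2. RNA or reads from lung tissue, which holds blood cells and macrophages, may explain this, with SFTPC at 2855 counts, CD74 at 1206, A2M at 1044 and DCN at 434. CD74, A2M and DCN were chosen after their values were seen. A response to shSNHG1#1 is argued against by the other shSNHG1#1 libraries, in which the median log2 ratio to shNC was -0.10 over 44 lung tissue genes, a list written after many of them were seen high in replicate 1. The step at which such RNA or reads entered stays open. Summed surfactant counts were 367 to 645 in the shNC and the other shSNHG1#1 libraries, but 3 to 11 with shSNHG1#2. The cause of that difference was not tested.

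Other splits of the libraries were fitted in the same way. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split gave 9023 genes for shSNHG1#1 against shNC where the highest other gave 0, 8669 for shSNHG1#2 where the highest other gave 0, and 586 between the hairpins where the highest other gave 1. For genes changed in the same direction by both hairpins, 1 of 100 splits drawn from 840, the real one, gave as many as 7500. These splits cannot exclude chance, because close replicates, which may be technical, leave almost no genes in a split that divides them. Chance between cultures is not covered by these splits, since the labels do not say that replicates were separate cultures. The highest other gave 7289, from the 1 other drawn split that kept the shNC libraries together, and the 98 that divided them gave at most 2. That split points to a structure in which the shNC libraries stand apart from the 6 others.

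The change against shNC differed between the hairpins for 586 genes and 11 lists, by the direct test of shSNHG1#2 against shSNHG1#1. Of the named genes, 41 differed, 27 higher with shSNHG1#2 and 14 lower. On the log2 scale the higher genes were MED4 at 1.101, LOX at 0.94, CACNA1B at 0.86, MUC16 at 0.81, MT1X at 0.67, IGFBP3 at 0.67, NDRG1 at 0.63, DHRS2 at 0.53, CA9 at 0.52, PARP9 at 0.49, ARRDC4 at 0.48, MX1 at 0.45, TXNIP at 0.44, ADM at 0.43, SOX2 at 0.43, IRF9 at 0.42, OAS3 at 0.41 and VEGFA at 0.39. Smaller differences were those of MUC5AC at 0.38, HK2 at 0.37, PDK1 at 0.34, FN1 at 0.33, IFI44 at 0.32, SLC2A1 at 0.22, BIRC2 at 0.20, MYC at 0.16 and STC2 at 0.15. The lower genes were SFTPC at -9.83, SFTPA1 at -9.49, SFTPB at -7.44, BIRC5 at -0.30, FDPS at -0.25, INSIG1 at -0.22, PMAIP1 at -0.21, SOD2 at -0.20, ENO1 at -0.16, PDIA4 at -0.13, CAD at -0.13, TNFAIP2 at -0.12, DERL1 at -0.12 and ALDH1A1 at -0.11. SFTPC, SFTPA1 and SFTPB were at -6.39, -6.05 and -4.52 without shSNHG1#1 replicate 1, and SFTPC and SFTPA1 at -12.96 and -10.32 without shSNHG1#2 replicate 1. MUC16, IGFBP3, CA9, VEGFA, MUC5AC, SLC2A1 and ALDH1A1 were chosen after their values were seen. Leaving out 1 library ended the call for 18 of the 41 genes and for none of the other 23. The highest adjusted p without 1 library was 0.226 for ALDH1A1, 0.219 for DERL1, 0.176 for SFTPA1, 0.167 for SFTPC, 0.155 for SOX2, 0.148 for SFTPB, 0.146 for MED4, 0.139 for PDIA4, 0.112 for STC2 and 0.0738 for ENO1, each without shSNHG1#2 replicate 2. It was 0.174 for CAD, 0.136 for TNFAIP2 and 0.0894 for INSIG1 without shSNHG1#2 replicate 3, 0.149 for PDK1, 0.128 for MYC, 0.0876 for BIRC2 and 0.0574 for FDPS without shSNHG1#1 replicate 3, and 0.0777 for CA9 without shSNHG1#1 replicate 1.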

How the results depend on the processing

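Leaving out the 2 most abundant features without a symbol was chosen only after seeing the data, and all other alternatives were planned. Under it 9013 genes passed with shSNHG1#1, 8648 with shSNHG1#2, 591 between the hairpins and 7486 in the same direction with both.

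DESeq2 size factors gave 4457 genes higher and 4568 lower with shSNHG1#1, and 4266 and 4388 with shSNHG1#2, so which direction held more genes depended on the scaling.

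A minimum change of 2-fold left 1159, 992, 37 and 712 genes in these comparisons, fewer by construction. Between the hairpins the DESeq2 Wald test gave 970 genes and a fit to the 2 groups compared gave 386, and the cause was not tested. With an estimated correlation 5 of 8, 5 of 10 and 4 of 11 lists passed, and the cause was not tested.

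Leaving out each library in turn gave 8051 to 8939 genes with shSNHG1#1, 7676 to 8753 with shSNHG1#2, 297 to 534 between the hairpins and 6701 to 7186 with both, and 8 to 9, 10 to 12 and 9 to 12 lists. Without shSNHG1#1 replicate 1, which held the lung surfactant transcripts, the counts were 8293, 8753, 417 and 7186. All these fits have fewer samples.

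The replicate numbers did not pair the libraries: same-numbered libraries had deviations correlated at -0.036 to 0.032, and 7 of 18 best matches had the same number. With the replicate block 8752, 8421, 433 and 7301 genes passed.

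Of 254 gene results and 29 list results, none reversed under any alternative run. Over all settings the genes kept their call in 3385 cases and lost it in 164, and the lists kept it in 354 and lost it in 22. DESeq2 gave no adjusted p for 22, 22 and 9825 genes, which were left out of the count of lost calls. At this depth a gene with few counts, such as STX5 in shNC or HSPA6 with each hairpin, has a fold that a single library can move.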

Other observations

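Genes of this part, apart from HMOX1, were chosen only after their values were seen, and their fold changes are from edgeR's planned test.

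Some genes for detoxifying enzymes and mucins were higher with both hairpins, and others were not. ALDH3A1, an aldehyde dehydrogenase gene, went from 824 ± 8.83 FPKM in shNC to 1525 ± 47.7 with shSNHG1#1 and 1516 ± 56.3 with shSNHG1#2 (SD, n = 3), and ALDH1A1 from 928 ± 13.7 to 1460 ± 25.4 and 1367 ± 16.1. AKR1B10, an aldo-keto reductase gene, rose 1.46-fold and 1.35-fold. The gel-forming mucin gene MUC5AC rose 1.94-fold and 2.52-fold from 70.6 ± 4.16 FPKM, and MUC16 1.32-fold and 2.31-fold from 1.097 ± 0.0929 FPKM. NQO1, a quinone reductase gene, stood at 650 ± 8.39, 680 ± 34.3 and 657 ± 31.5 FPKM in shNC, shSNHG1#1 and shSNHG1#2, and HMOX1, a heme oxygenase gene, fell from 122 ± 3.94 FPKM to 68.3 ± 4.23 and 61.1 ± 2.82. No list fixed beforehand held the genes named here as higher, and the glutathione and metallothionein list, which holds NQO1 and HMOX1, did not pass against shNC (adjusted p = 0.796 and 0.961).

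HIF1A, which encodes the oxygen-regulated subunit of a hypoxia-inducible factor, moved against the hypoxia genes: its transcripts rose from 40.3 ± 1.01 FPKM in shNC to 151 ± 8.82 with shSNHG1#1 and 137 ± 2.01 with shSNHG1#2 (SD, n = 3). CA9 fell 5.04-fold and 3.52-fold, SLC2A1, a glucose transporter gene, 5.04-fold and 4.32-fold, and VEGFA 2.79-fold and 2.13-fold. IGFBP3, which binds insulin-like growth factors, fell from 2134 ± 18.7 FPKM to 558 ± 9.58 and 909 ± 4.23.

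A single feature without a gene symbol held 6.57% to 7.09% of all counts in the shNC libraries and 11.8% to 13.5% in the 6 shSNHG1 libraries. A second such feature held 0.498% to 0.545% in shNC and 1.02% to 1.21% in the others. All features without a symbol together held 8.18% to 8.78% in shNC and 13.96% to 15.9% in the others.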
